A study of Mus musculus with 4 samples.

How the data were processed

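CTCF occupancy was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in hippocampus of C57/Bl mice. CTCF is a zinc finger protein that binds DNA and, together with the cohesin complex, shapes chromatin loops. The labels list 2 ChIP libraries, made with an anti-CTCF antibody and a tissue immunoprecipitation kit, and 2 input libraries, which are chromatin sequenced without immunoprecipitation. The series text describes replicates from mice and counts a single input, whereas the sample labels name 2 inputs.

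The values used were 1 peak list deposited for the whole series. Per the submitters' processing notes, cutadapt, MACS2 version 2.0.10.20131216 and the mouse genome build mm9 were used. Per the file header, the list is in narrowPeak style on mm9, and its name joins ChIP 1 and 2 against input 1 and 2. The peaks were therefore called on combined samples, and no position, score or depth of any single library was given. The aligner, the treatment of duplicate reads, the calling threshold and any exclusion of problem regions are not given in the sources used here. Each peak carries a start, an end and a whole-number score as deposited by the authors. The scaling of the score is not stated in the header, so the score was used only to describe, rank and filter peaks inside this list.

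Starts were converted from the zero-based BED convention to positions counted from 1. The span of a chromosome was taken from the start of its first peak to the end of its last, since no chromosome lengths or assembly gaps of mm9 were used here. Densities are peaks per Mb of span, with exact Poisson 95% intervals that cover counting error only. Chromosomes were compared by counting peak midpoints in full 5 Mb windows of the span. The mean count per window of each autosome was compared with that of the other 18 autosomes, and X with all 19 autosomes, in a two-sided permutation test with 100000 shuffles of the window labels. Ratios of window means have 95% bootstrap intervals from 10000 resamples of windows. Scores were compared between each chromosome and all other peaks by mean rank, with 100000 shuffles. All 20 chromosomes formed 1 family for each measure, adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Neighbouring windows and peaks are not independent, so these p-values are too small by an unknown amount. The bootstrap intervals treat windows as independent and are too narrow for the same reason. Both describe this list rather than a population of mice.

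Spacing was the share of peaks with another peak midpoint within 10 kb. It was compared with 1000 random placements in which every peak kept its width and chromosome and could overlap others. The smallest two-sided p that these placements can give is 0.0020. The relation of score to spacing was tested with 10000 shuffles of scores within chromosomes, as was the rank correlation of the scores of adjacent peaks.

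The spacing test was tested on simulated lists of 15109 peaks. It called 1 of 50 lists placed at random, and 50 of 50 lists in which 10% of the peaks had been moved next to another. The lists placed at random were drawn as in the test itself, so their rate checks the calculation only. The window test was tested on simulated windows drawn independently of each other. Their mean was the density over all chromosomes, X included, and their relative spread was taken from the autosomal windows. It called chromosome 5 in 19 of 20 sets when its density was set to 0.125 of the others, in 12 of 20 sets at a ratio of 2, and in 0 of 20 sets at a ratio of 0.5. Among the 360 tests of unchanged chromosomes at each ratio, it made 4, 0 and 2 calls, in the same order. The simulations used fewer shuffles and placements than the tests themselves. In the simulated windows the adjustment covered the 19 autosomes, without X. Neighbouring windows of the list are not independent, so these calls do not show how the test behaves under such dependence.

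The counts with their alternatives for score and joining, the naming of the 20 highest-scoring peaks, and the measure of spacing with its alternatives for distance and score were fixed before the data were examined. The random placement departed from the plan, which was to place peaks over the whole chromosome outside assembly gaps. Without the lengths and gaps of mm9, the span from first to last peak was used, gaps inside it included. The comparison of chromosomes, the 1 Mb windows and the peak-free stretches were chosen after the peak list had been seen. The rule for named items gave each of the 20 peaks with the highest score by its coordinates. The rule also fixed 3 genes and members of gene lists, but no mm9 sequence or gene annotation was used here. The planned comparisons with promoters, gene bodies, gene lists and the CTCF motif were therefore not run, and peaks carry no gene names. The gene table provided for reference is on another build (GRCm38.p6) and was not used. Read depth is unknown from the peak list. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.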

Results

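The design asked where in the hippocampal genome CTCF was enriched over input chromatin. The hippocampus is the brain region needed for forming new memories. A single list of CTCF peaks was obtained from 2 ChIP and 2 input libraries combined, so no value below has a replicate error. The list held 15109 peaks on the 19 autosomes and chromosome X. No peak lay on chromosome Y or on mitochondrial DNA. The peaks covered 8.33 Mb, which was 0.327% of the chromosome spans. Their median width was 473 bp, with an interquartile range of 399 to 605 bp and a maximum of 3420 bp. The smallest width, 344 bp, was shared by 568 peaks, and 869 peaks (5.75%) were wider than 1 kb. The authors' peak score ran from 13 to 3888 with a median of 93, so that most scores lay far below a long upper tail. Strong and weak, here and below, mean high and low by this score alone. Wider peaks had higher scores (Spearman's rho = 0.59 across peaks, permutation p = 1e-04, the smallest that 10000 shuffles can give). Peaks are not independent replicates.

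The strongest CTCF peak in the list lay on chromosome 9 at 121605687 to 121607893 (mm9), with a score of 3888 and a width of 2207 bp. The next was on chromosome 17 at 34271498 to 34273147, with a score of 3868. It was followed by a peak on chromosome 4 at 134033251 to 134035709, which scored 3590 and was 2459 bp wide. Chromosome 7 carried the fourth, at 117307520 to 117309435, with a score of 3277. A further peak on chromosome 9, at 111191834 to 111193392, scored 2924. The peak on chromosome 3 at 104795188 to 104796486 scored 2858. On chromosome 11, the peak at 61317781 to 61319049 scored 2787. On chromosome 1, the peak at 21208071 to 21209454 scored 2782.

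The 20 highest-scoring peaks had scores of at least 2521 and widths of 1214 to 2459 bp, and they lay on 10 chromosomes. Chromosome 11 held 6 of them, at 61317781, 103019776, 94839799, 115947623, 95394272 and 22517041. It held 9.31% of all peaks, and its scores did not differ detectably from the others by mean rank (adjusted permutation p = 0.71). The count of 6 was not tested. Chromosomes 7, 9, 13, 14 and 19 held 2 each, and chromosomes 1, 3, 4 and 17 held 1 each. None was on X. Another peak lay within 10 kb of 8 of the 20. The neighbour of the chromosome 9 peak at 121605687 was 4.67 kb away and scored 90, and that of the chromosome 4 peak was 4.62 kb away and scored 24. In contrast, the chromosome 14 peak at 34026516, with a score of 2667, had a strong neighbour 8.36 kb away that scored 1300. The chromosome 7 peak at 87487286, with a score of 2547, had one 3.08 kb away that scored 1027. The chromosome 13 peak at 21291792 stood alone, with 163 kb to the nearest peak.

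CTCF peaks were spread unevenly over the chromosomes. Chromosome 11, among the more gene-dense mouse chromosomes, had the highest density, with 1406 peaks or 11.9 per Mb (95% Poisson interval 11.3 to 12.5). Chromosome X had the lowest, with 135 peaks or 0.847 per Mb (0.710 to 1.002), against 6.28 per Mb over all autosomes. The sparsest autosome, chromosome 3, had 500 peaks or 3.30 per Mb (3.02 to 3.60), still 3.90 times the density of X. Chromosomes 5, 4, 17 and 19 followed chromosome 11 with 8.64, 8.48, 8.46 and 8.11 peaks per Mb. Chromosomes 13, 1 and 14 were nearest to chromosome 3, with 3.89, 3.94 and 4.03 peaks per Mb.

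**Figure D1:**
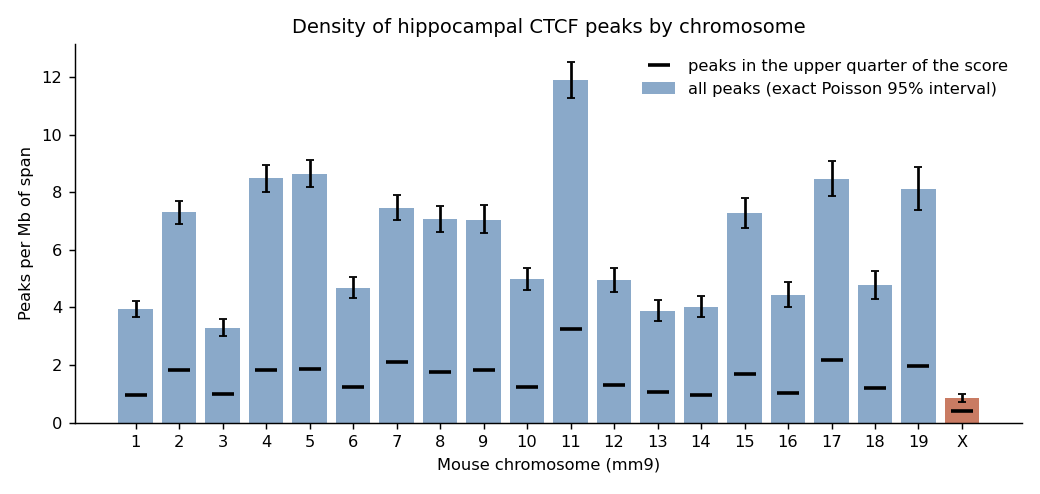
Peaks per Mb of chromosome span (vertical axis) for each mouse chromosome on mm9 (horizontal axis). Bars show all peaks with exact Poisson 95% intervals, and black dashes show peaks with a score of 163 or more. Chromosome 11 is highest at 11.9 per Mb and X lowest at 0.847 per Mb.

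Counts also varied widely along each chromosome. Chromosome X held 3.90 ± 4.74 peaks per 5 Mb window (SD, n = 31 windows), against 30.9 ± 37.0 on the autosomes (n = 462 windows). This was a ratio of 0.126 (95% bootstrap interval 0.0755 to 0.185), and X fell below the autosomes in the permutation test (adjusted p = 0.0062). The ratio was 0.242 among peaks scoring 163 or more and 0.0670 among those under 93, with X lower and past the threshold in both. Chromosome 11 held 57.5 ± 55.9 peaks per window (n = 23 windows), 1.95 times the other autosomes (1.26 to 2.83), and was past the threshold (adjusted permutation p = 0.014). The other 18 autosomes were not, with ratios from 0.514 (0.326 to 0.764) on chromosome 3 to 1.46 (0.824 to 2.34) on chromosome 17. For chromosomes 1, 3, 13 and 14 the bootstrap interval lay below 1, although the test did not pass (adjusted permutation p from 0.19 to 0.31). These intervals treat windows as independent and are too narrow, so they do not by themselves show a lower density. In simulated windows of similar spread, drawn independently, chromosome 5 with its density set to 0.5 of the others was called in 0 of 20 sets. The test therefore had little power in such windows for a difference of that size on a chromosome with 29 windows.

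The few peaks on X had higher scores, by rank, than the other peaks, but no marked excess among the very strongest. Their median score was 154, against 93 for all other peaks, and 47.4% of them scored 163 or more, against 25.2% on the autosomes. At scores of 569 or more the shares were close, with 8 of the 135 X peaks (5.93%) against 4.995% of the autosomal peaks. The difference in mean rank was past the threshold (adjusted permutation p = 2e-04). Among autosomes, median scores ranged only from 90 to 98.5. Chromosome 4 had lower scores than all other peaks by mean rank (difference -490 ranks, adjusted permutation p = 0.0011). Its median was 90 against 94, and 21.6% of its peaks scored 163 or more. These 2 summaries do not set it apart. Chromosomes 2, 5, 6, 10 and 12 had the same median, and 21.7% of the chromosome 5 peaks scored 163 or more (adjusted permutation p = 0.39). The remaining 18 chromosomes did not pass, chromosome 7 being closest with medians of 97 and 93 (adjusted permutation p = 0.0501).

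Autosomes dense in weak peaks tended to be dense in strong ones, in a similar but not identical order. Across the 19 autosomes, the density of peaks scoring 163 or more rose with that of the weaker peaks (Pearson's r = 0.94, Spearman's rho = 0.89, adjusted permutation p = 2e-05 for both). Without chromosomes 11 and 3 the correlation was 0.92. Both densities are parts of the same list over the same spans. The share of peaks scoring 163 or more ranged only from 21.6% to 30.4% on autosomes, so a high correlation largely follows. It is therefore no separate evidence on strong against weak peaks. The share of peaks scoring 163 or more showed no detectable relation to density (r = -0.20, adjusted permutation p = 0.42, and rho = -0.22, adjusted permutation p = 0.37). Without the same chromosomes, r was -0.29. These 2 relations were the only ones computed across chromosomes.

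At a finer scale, CTCF peaks were concentrated in some regions and missing from long stretches. The following regions were chosen after their values had been seen. The fullest 1 Mb window, on chromosome 4 from 140000001 to 141000000, held 75 peaks, 14 of which scored 163 or more. The next were on chromosome 11 from 117000001 to 118000000 with 67 peaks, and on chromosome 8 from 122000001 to 123000000 and chromosome 17 from 27000001 to 28000000 with 63 each. The chromosome 8 window was also rich in strong peaks, 25 of its 63 scoring 163 or more, and the 2 windows after it held 52 and 59 peaks. A window on chromosome 2 from 32000001 to 33000000 held 62. Of the 2525 full windows, 82 held more than 30 peaks, the highest count that any window reached in 1000 random placements. Chromosome 4 had 14 of these windows, chromosome 5 had 12, chromosome 2 had 11, chromosome 11 had 10, and X had none. The 252 fullest windows together held 49.1% of the peaks in full windows.

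**Figure D2:**
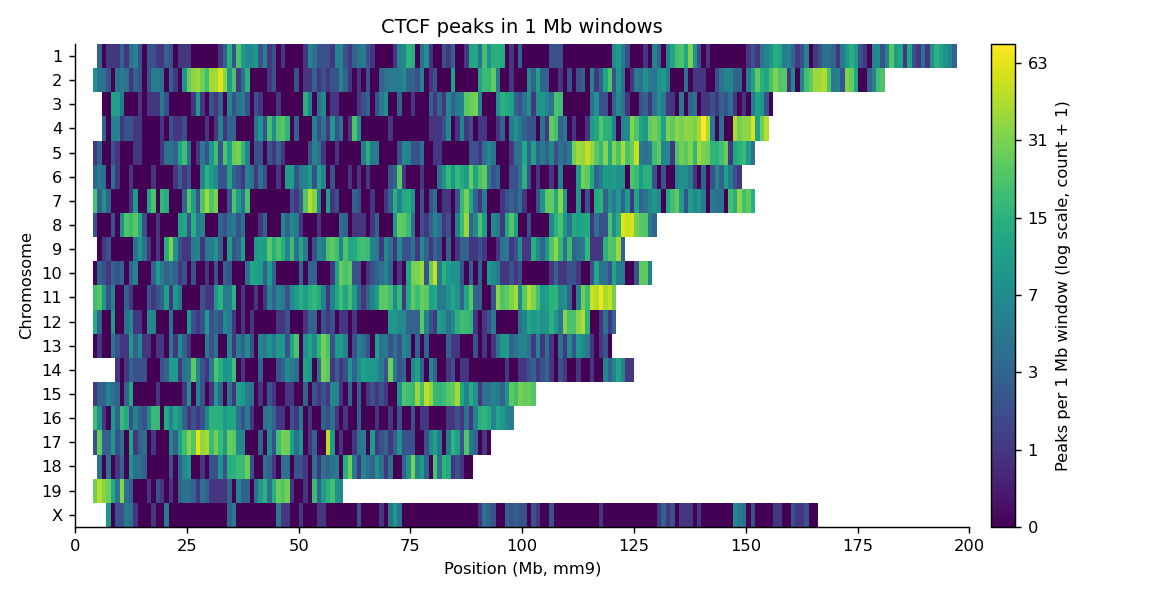
Peaks in 1 Mb windows along each chromosome (vertical axis), with position in Mb on mm9 on the horizontal axis and colour giving the number of peaks on a log scale of the count + 1. White marks positions outside the first and last full window. The fullest window, on chromosome 4, holds 75 peaks, and most windows of X hold none or a few.

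Empty windows were also frequent, with 761 of 2525 (30.1%) holding no peak, against a mean of 86.7 and at most 106 in random placements (permutation p = 0.0020). The longest stretch between adjacent peaks was on X, from 72919392 to 90526609, and measured 17.6 Mb. X also held stretches of 13.8 Mb from 20539505 and 13.03 Mb from 117404261, and 5 of the 10 longest in all. The longest on an autosome, 11.6 Mb, was on chromosome 1 from 108609405 to 120218195. Of the 38 stretches above 5 Mb, 7 lay on X and covered 80.9 Mb of its span of 159 Mb.

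CTCF peaks lay closer together than randomly placed ones. Another peak was found within 10 kb of 6477 peaks (42.9%), against 12.9% on average and 13.9% at most in 1000 placements (permutation p = 0.0020). This was a ratio of 3.32 to placement over whole chromosomes. The ratio was smaller, 1.46 and 1.18, against placement of each peak inside its own 1 Mb or 100 kb window, alternatives added after seeing the data (permutation p = 0.0020 for both). Over whole chromosomes, within 5 kb the share was 28.4% against 6.71%, a ratio of 4.24, and within 50 kb it was 77.1% against 48.9%, a ratio of 1.58. Some of these neighbours lay next to each other: joining peaks with under 1 kb between them gave 14187 regions, 830 of which held more than 1 peak. The region with the most, on chromosome 19 from 6260175 to 6264861, held 5 peaks over 4.69 kb, none scoring above 113. A region on chromosome 5 from 125747320 to 125752926 held 4 peaks, the strongest of which scored 840. After joining, 36.4% of regions still had another within 10 kb, against 12.1% with placement over whole chromosomes, 27.0% inside 1 Mb windows and 32.7% inside 100 kb windows (permutation p = 0.0020 for each).

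**Figure D3:**
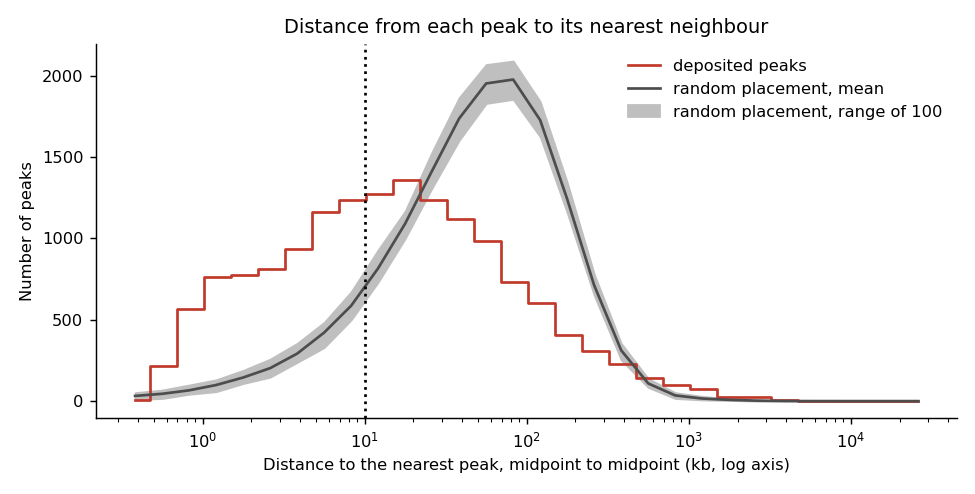
Number of peaks (vertical axis) by distance to the nearest other peak in kb, midpoint to midpoint (horizontal log axis). The red line shows the deposited peaks, the grey line and band the mean and range of 100 random placements, and the dotted line 10 kb, within which 42.9% of the deposited peaks have a neighbour.

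Peaks with a neighbour within 10 kb were slightly weaker than the 8632 others. Their median score was 90 against 97, and 23.7% of them scored 163 or more against 26.6% (permutation p = 1e-04 for the difference in mean rank, the smallest possible with 10000 shuffles). This comparison used peaks before joining, so weak peaks split from a strong one may contribute to the difference, which was not tested. The scores of adjacent peaks were almost unrelated. The rank correlation was 0.064 over 4042 pairs up to 10 kb apart, 0.050 over 7128 pairs at 10 to 100 kb, and 0.043 over 3919 pairs farther apart. Each was past the threshold, with adjusted permutation p-values of 1.5e-04, 1.5e-04 and 0.012 over the 3 relations.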

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

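The number of peaks fell from 15109 to 7602 when only scores of 93 or more were kept and to 3832 with scores of 163 or more, which follows from the filters themselves, and was 14187 after joining peaks under 1 kb apart. The excess of close neighbours kept its direction and its side of the threshold under all 9 alternatives, with shares from 26.2% (scores of 93 or more, against 6.71% at random) to 77.1% (50 kb). Its size did depend on the placement: the ratio to the random share fell from 3.32 to 1.46 inside 1 Mb windows and 1.18 inside 100 kb windows, where the observed 42.9% is the same by construction, and for joined regions from 2.995 to 1.35 and 1.11. The ratio of X to autosomal density stayed below 1 and past the threshold under all 6 alternatives, from 0.0670 among scores under 93 to 0.242 among scores of 163 or more. The ratio for chromosome 11 stayed between 1.94 and 2.18 under all 5 of its alternatives, although its adjusted permutation p reached 0.045 with 10 Mb windows. The alternatives for X and chromosome 11, and for spacing the placements inside windows, the joining and the list without X, were chosen after seeing the data. No paired analysis was possible because the list combines the libraries and gives no value for any of them. For the same reason leaving out a replicate was not run. The alternatives for promoters, gene lists, gene bodies, motif share and motif orientation were not run, since no mm9 sequence or annotation was used here. Read depth is unknown, so the reads behind a weak peak or an empty region cannot be stated, and an empty stretch is not evidence of absent binding.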

Other observations

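The copy number explanation and the test on the distal part of chromosomes were added only after the result was seen. No test of copy number was run. The X ratios at scores of 569 or more and under 62 had no outcome written down in advance. Nor had the 100 kb placements of joined regions. The outcomes of the X ratio at scores of 163 or more, the X ratio over occupied windows and the 1 Mb placements of peaks and of joined regions were written down before their values were computed, but after the patterns had been noticed.

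On the map of windows, several autosomes carried most peaks in the part away from the centromere, which in mouse lies at the low-coordinate end. The distal 50% of the span held 84.6% of the peaks on chromosome 15, 83.3% on chromosome 4, 77.6% on chromosome 5, 76.8% on chromosome 12, 76.5% on chromosome 8 and 74.1% on chromosome 11. Chromosomes 17, 16, 14 and 13 went the other way, with 28.3%, 29.5%, 31.6% and 37.1%. The mean over autosomes was 59.2% ± 18.4 (SD, n = 19), above 50% on 13 of 19 (exact sign-flip permutation p = 0.044). Among peaks scoring 163 or more the mean was 58.8%, above 50% on 12 of 19 autosomes, and did not pass (exact sign-flip permutation p = 0.075). A general distal lean is therefore no more than a hypothesis from these data.

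The low number of peaks on X was the largest departure among chromosomes, at a ratio of 0.126 to the autosomes. A loss of only weak peaks below the calling threshold would leave the strong ones at autosomal density. Among peaks scoring 163 or more the ratio was 0.242 (95% bootstrap interval 0.130 to 0.370). At scores of 569 or more it was 0.147 (0.0599 to 0.250, from 8 X peaks). Both argue against a loss confined to weak peaks with the strong ones unchanged. A lower signal over all of X would also lower the scores used for these filters. The ratios therefore cannot decide whether a loss at the threshold of that kind took place. Yet the X peaks that remained scored higher, with a median of 154 against 93 for all other peaks. At 163 or more the shares were 47.4% on X and 25.2% on autosomes, and at 569 or more 5.93% and 4.995%. This argues against a uniformly lower signal as the whole account. The calling threshold is not known, which limits the comparison of the remaining peaks. For scores under 62 the ratio was 0.0542 (0.0204 to 0.0960). A few large empty stretches would leave windows outside them as full as on autosomes. Over windows with at least 1 peak the ratio was 0.173 (0.114 to 0.241). Windows that lie partly inside an empty stretch are among these, so the stretches themselves may account for part of this low ratio. A lower copy number of X, as in males, would be a form of such a lower signal. It may contribute and stays open, because neither the sex of the mice nor reads per chromosome were among the values used. Other properties of X, such as its base composition or chromatin, were not tested.

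The closeness of neighbouring peaks was weighed against 2 explanations. If it only reflected density that varies between 1 Mb windows, placing each peak at random inside its own window would give the same share. Such placements gave 29.3% on average and at most 30.9%, against 42.9% observed, so it accounted for part of the excess over 12.9% but not for all of it. Binding regions split by the peak caller would add close pairs on top of this density, and the comparison of joined regions with placement over whole chromosomes cannot separate them. When joined regions were placed inside their own 1 Mb windows, the placements gave 27.0% on average and at most 28.2%, against 36.4% observed, so splitting at under 1 kb and 1 Mb density together left an excess. Inside windows of 100 kb the placements of joined regions gave 32.7%, at most 34.1%, and the remaining excess may reflect promoters or other elements at a finer scale, which were not tested.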
